A study of Mus musculus with 6 samples.

How the data were processed

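RNA was sequenced from haematopoietic stem and progenitor cells sorted by flow cytometry from mouse bone marrow, with a TruSeq RNA kit on a NovaSeq instrument, per the labels. The 6 libraries fall into 2 groups of 3, wild type and Robo1 knockout, as each sample's description gives them. The sample titles and treatment field describe the same libraries as shRNA control and shRNA knockdown. The titles name ROBO1 for every knockout library, and the treatment field names ROBO1, ROBO2 and ROBO3 in turn. The series' design text and genotype field instead describe a knockout made with Mx1-cre. Groups and replicate numbers here follow the descriptions.

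The authors deposited 1 table of 18491 genes. It holds raw read counts per gene and library, a length-scaled value per gene and library, and the columns of the authors' own DESeq2 comparison. The submitters' processing notes name fastp 0.22.0, HISAT2 2.2.1, featureCounts 2.0.1, DESeq2 1.32.0 and the mouse genome build mm10, without giving their order or options. Whether reads were counted by strand is not given in the sources used here, so overlapping and antisense genes cannot be separated with certainty. The length-scaled values carry no unit in the file header. They were taken as FPKM because, for genes with a single annotated transcript, at least 98.7% of the values in each library lay within 1% of one constant multiple of the FPKM computed from the deposited counts (758 to 761 such genes per library, mean normalized count of at least 500). The authors' deposited log2 fold changes, with their standard errors, and p-values come from that comparison and were used only to describe that table. Its mean signal per gene is, as deposited, the mean over the libraries of counts divided by size factors, and its test score is, as deposited, the log2 fold change over its standard error. Its adjusted p-values equal a Benjamini-Hochberg adjustment over its 18491 rows to within 1%.

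Gene IDs were matched to the GENCODE vM21 annotation of GRCm38, the assembly also called mm10. Of the 18491 IDs, 18470 matched and 21 did not, and 24 symbols stood on more than one row. Exon length and GC content were available for 99.8% of the genes.

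The deposited counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its default settings, which left 15474 genes. Libraries were scaled with TMM and tested with the quasi-likelihood test (glmQLFit and glmQLFTest), two-sided, with group as the only term. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. CPM values use the TMM-scaled library size unless total counts are named. A fold change for a gene with no count in a group is a lower bound set against 3 counts over that group, and covers counting error only. These bounds use TMM-scaled library sizes and were not computed with total counts.

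The 26 gene lists were fixed before the data were examined. For 25 of them, with at least 5 tested members, camera of limma 3.58.1 was run on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01. The p-values were adjusted over the 25 lists. Camera with an estimated correlation and fry were run beside it. With an estimated correlation, camera also takes its degrees of freedom from the libraries, which are few, and not from the genes. Of the 25 lists tested, 1 is not described here, and some genes chosen by the rule below are not described either. The named genes were also fixed by rule before the data were examined. They are Robo1 to Robo4 and Cdc42, the 10 largest rises and 10 largest falls among called genes with non-overlapping groups and a mean of at least 1 CPM, without predicted gene models, Rik clones and pseudogenes, and up to 4 members of lowest p from each list. Because 9 of the 10 largest rises were immunoglobulin V genes, the 10 largest changes per direction outside immunoglobulin genes were added after the values were seen. Members of lists named beyond the 4 of lowest p, and the immunoglobulin constant genes, were also chosen after their values were seen.

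The procedure was tested on simulated counts drawn from the means and dispersions of the 6 libraries, with 14643 genes tested and 200 changed by known folds. In this simulated knockout against wild-type comparison 26.9% of the genes changed by 1.5-fold were called, 77.6% of those changed by 2-fold and 93.9% of those changed by 4-fold. Of the calls, 7.04% were false. The 1 list given a shift was called and 0 of the other lists were. Every gene was drawn independently, so the simulation could not show false list calls that arise from correlation between genes. Far fewer genes changed than were called in the real data, and no shift in composition between the groups was simulated. The choice of scaling was therefore not tested, and the shares recovered need not hold for the real comparison.

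Library totals ran from 42235077 to 58106099 counts. No library was a copy of another, since the counts of every pair within a group differed by 13.8 to 39.4 times the variance that sampling alone gives (chi-square per gene over genes with at least 20 counts in the pair).

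Alternatives listed before the data were examined were RLE and upper-quartile scaling, no filter, a filter of at least 1 CPM in 3 samples, the replicate number as a block, each library left out in turn, DESeq2 1.42.0, limma-voom, robust dispersions, a fold change of at least 2, an adjusted p under 0.1, an estimated correlation and fry. Added after the data were seen were scaling by total counts alone, removal of immunoglobulin genes, and a correction per library for exon length and GC content with splines of 5 degrees of freedom. Python 3.11.15 with pandas 2.3.3 read the table, and matplotlib 3.10.9 drew the figures.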

Results

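Gene expression was measured by RNA sequencing in cells labelled as haematopoietic stem and progenitor cells, the bone marrow cells from which all blood lineages arise. The purity of the sort was not tested. Immunoglobulin genes, which belong to the B lineage, took 2.72 ± 0.0429% of counts in wild type and 3.57 ± 0.0848% in knockout (mean ± SD, n = 3 each). The cells were sorted from mice 8 months after poly(I:C), a synthetic double-stranded RNA given in 3 doses. Poly(I:C) switches on the Mx1-cre recombinase, which was used to delete Robo1, a receptor for the Slit family of guidance proteins. There were 3 wild-type and 3 Robo1 knockout libraries. Total counts were 44578916, 54005098 and 58106099 in wild type and 57058267, 51654303 and 42235077 in knockout. The labels do not say whether the libraries came from separate animals, so p-values here measure only the spread between these libraries, which may be technical.

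The targeted gene, Robo1 (chromosome 16, 72308306 to 73046095, plus strand, GRCm38), and Robo2 were not analysed here, so the genotype labels were not checked against the transcript they name. The related receptors were close to the detection limit. Robo3 stood at 0.755 ± 0.298 CPM in wild type and 1.02 ± 0.556 CPM in knockout (mean ± SD, n = 3 each, edgeR adjusted p = 0.553). Robo4 stood at 0.256 ± 0.169 and 0.405 ± 0.508 CPM (n = 3 each, edgeR adjusted p = 0.74). Neither difference was detectable at this depth.

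The main comparison asks how the transcriptome of cells sorted as stem and progenitor cells differs between Robo1 knockout and wild type. With TMM scaling 85 of 89 ribosomal protein genes, 12 of 24 basophil, mast cell and eosinophil genes and 17 of 35 immediate early and heat shock genes rose in knockout, and 22 of 45 interferon-stimulated genes fell. With an estimated correlation between genes camera called none of these lists (adjusted p = 0.209, 0.095, 0.101 and 0.095). The estimated correlations were, in the same order, 0.58, -0.033, 0.018 and -0.021. Those of the basophil and interferon lists lay below the preset 0.01, so correlation between genes does not account for their lost calls. Prg2, which encodes the eosinophil major basic protein, rose 7.70-fold, from 5156 ± 595 to 39685 ± 2839 CPM (mean ± SD, n = 3 each). Fos, an immediate early transcription factor, rose 6.68-fold, from 559 ± 42.9 to 3734 ± 319 CPM. Igtp, an interferon-induced GTPase, was 2.32-fold lower in knockout, at 10.5 ± 0.387 CPM against 24.5 ± 1.44 CPM.

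Of 15474 genes tested, 4898 changed in edgeR's quasi-likelihood test, 2669 higher and 2229 lower in knockout. The change was at least 2-fold for 1278 of the higher and 534 of the lower genes. In 2650 of the higher and 2215 of the lower genes every knockout library lay beyond every wild-type library. Without wild type replicate 2 the lower genes numbered 1356, and without wild type replicate 3 they numbered 1419.

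The libraries of the 2 groups also differed in composition. The 100 most abundant genes took 42.9 ± 0.595% of counts in wild type and 60.3 ± 0.583% in knockout (n = 3 each), and the number of genes with a count was 17418 to 17671 against 16232 to 16609. Fold changes are given relative to TMM scaling, under which the median gene changed by -0.09 on the log2 scale. With total counts as the only scaling the median log2 fold change moves by -1.13, to -1.22, and 655 genes were called higher and 10937 lower, so that higher genes made up 5.65% of calls in place of 54.5%. The 655 genes were called higher under both scalings and 2229 genes lower under both, while 1177 genes were called higher with TMM and lower with total counts.

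**Figure D1:**
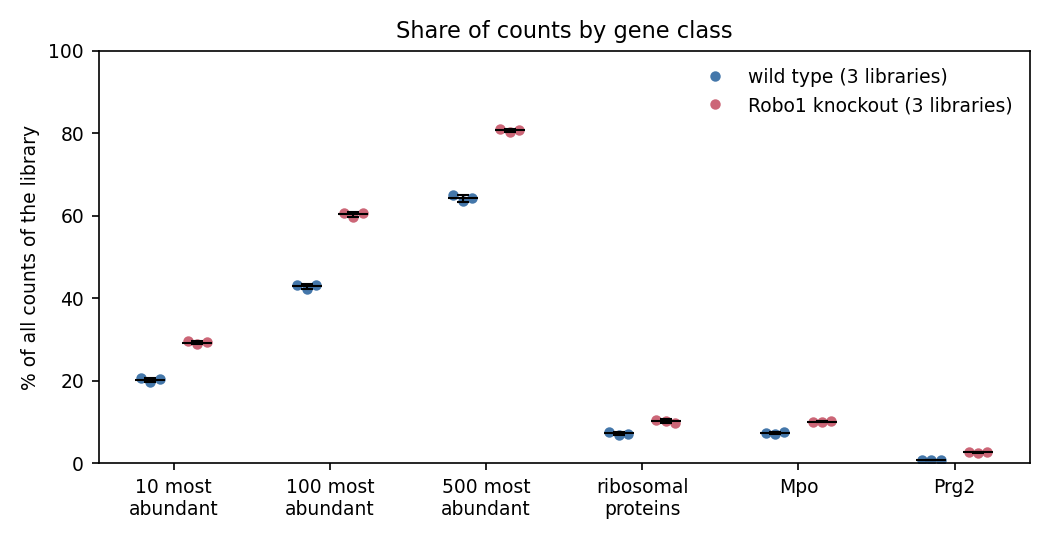
Share of each library's counts, in percent, taken by the 10, 100 and 500 most abundant genes, by ribosomal protein genes, and by Mpo and Prg2. Points are libraries and black bars the mean ± SD of 3 libraries; the 100 most abundant genes took 42.9% in wild type and 60.3% in knockout.

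Of 24 measured genes of basophils, mast cells and eosinophils, 12 rose, 2 fell and 10 did not pass (14 rose and 4 fell adjusted over the list alone). With total counts the median was -0.35, with 6 members called higher and 11 lower, though camera still called the list higher relative to the other genes. Epx, eosinophil peroxidase, rose from 415 ± 35.6 to 2758 ± 114 CPM (n = 3 each), Ear1, an eosinophil-associated ribonuclease, rose from 103 ± 5.45 to 1484 ± 100 CPM, and Prg3 rose from 405 ± 4.90 to 2000.1 ± 56.7 CPM. These 3 genes were also higher with total counts (log2 1.60, 2.71 and 1.17). The basophil protease gene Mcpt8 rose by a log2 fold change of 1.20 (SE 0.06), but by 0.07, not a call, with total counts. The members that fell were Cebpe, a transcription factor of granulocyte maturation, and Rgs18. The median log2 fold change was 0.79 and camera called the list (adjusted p = 2.56e-05, and adjusted p = 0.095 with an estimated correlation). Ear1, Ear2, Ear6 and Ear10 lie on chromosome 14 and are near-copies that can share reads, so their separate values are uncertain.

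Of 31 neutrophil and granulocyte progenitor genes, 19 rose, 5 fell and 7 did not pass (20 and 5 adjusted over the list alone). With total counts the median was -0.50, with 6 members called higher and 20 lower, and camera again called the list higher relative to the other genes. By counts Mpo, myeloperoxidase, was the most abundant of these, at 7.36 ± 0.217% of all counts in wild type and 10.1 ± 0.185% in knockout. By FPKM, which allows for length, Elane stood above Mpo, at 39636 against 22601 in wild type and 49963 against 30927 in knockout. The granule protease genes Ctsg (log2 2.04, SE 0.06), Prtn3 (2.01, SE 0.09) and Elane (1.46, SE 0.07) rose under both scalings, whereas Ms4a3 (1.11) stood at -0.02 with total counts. Camera called the list (median 0.63, adjusted p = 2.08e-05, and adjusted p = 0.162 with an estimated correlation), but not after the correction for exon length and GC content, which left a median of 0.29.

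Ribosomal protein genes moved nearly together, with 85 of 89 higher, 1 lower and 3 not passing (85 and 1 adjusted over the list alone). Rpl4 rose from 2394 ± 104 to 8925 ± 204 CPM and Rps6 from 1116 ± 24.4 to 3372 ± 40.7 CPM (n = 3 each). The median log2 fold change was 1.51 with TMM and 0.38 with total counts, where 61 members were called higher and 9 lower. Camera gave an adjusted p = 8.62e-38, and an adjusted p = 0.209 with an estimated correlation. Many of these genes have processed pseudogenes that can take or lend reads.

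Of 79 oxidative phosphorylation genes, 64 rose, 1 fell and 14 did not pass (67 and 1 adjusted over the list alone). The ATP synthase subunit genes Atp5b (log2 2.07, SE 0.07) and Atp5g3 (1.97, SE 0.06) led. The median was 0.57 with TMM and -0.56 with total counts, where 8 members were called higher and 64 lower. Camera called the list with TMM (adjusted p = 7.58e-19, and adjusted p = 0.162 with an estimated correlation) but neither with total counts nor after the length and GC correction. Of 13 mitochondrially encoded genes, 11 rose, 0 fell and 2 did not pass (12 and 0 adjusted over the list alone), with mt-Co3 rising from 2501 ± 235 to 16645 ± 5.97 CPM (n = 3 each). That list was called (median 1.52, adjusted p = 1.84e-08, and adjusted p = 0.273 with an estimated correlation), but not after the length and GC correction.

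Replication-dependent histone genes gave 30 higher, 2 lower and 28 not passing of 60 (34 and 2 adjusted over the list alone). H2bc4 rose by a log2 fold change of 0.91 (SE 0.07), but stood at -0.22 with total counts. Members were drawn by a pattern of gene names. That pattern also took in the linker histone gene H1f0, which is not replication-dependent and fell by 2.12 (SE 0.24). The list was called higher (median 0.95, adjusted p = 4.88e-06, and adjusted p = 0.493 with an estimated correlation). With total counts its median was -0.18, with 2 members called higher and 20 lower, though camera, which compares a list with the other genes, still called it higher. After the length and GC correction camera called it lower, at a median of 0.11. Histone genes are near-copies of one another and their separate values are uncertain.

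Of 35 immediate early and heat shock genes, 17 rose, 2 fell and 16 did not pass (18 and 2 adjusted over the list alone). Jun rose 4.20-fold, from 823 ± 11.2 to 3458 ± 49.2 CPM (n = 3 each), and the chaperone gene Hspa8 rose from 3430 ± 64.7 to 10531 ± 386 CPM. Ier2 went the other way and fell to 0.501 times its wild-type level of 83.9 ± 8.27 CPM. Camera gave an adjusted p = 3.42e-05 at a median of 0.55, and an adjusted p = 0.101 with an estimated correlation. Among NF-kB and inflammatory genes 18 of 39 rose, 3 fell and 18 did not pass (19 and 3 adjusted over the list alone), led by Nfkbia, the NF-kB inhibitor, at a log2 fold change of 2.34 (SE 0.07) and by S100a8 at 1.85 (SE 0.07). S100a8 is also on the neutrophil list. Camera called the NF-kB list at a median of 0.49 (adjusted p = 1.08e-04, and adjusted p = 0.101 with an estimated correlation). With total counts the medians of both lists were below 0, at -0.58 with 8 members called higher and 20 lower for the immediate early list, and at -0.64 with 3 higher and 22 lower for the NF-kB list, though relative to the other genes camera still called both higher.

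Of 45 interferon-stimulated genes, 22 fell, 2 rose and 21 did not pass (24 fell and 3 rose adjusted over the list alone). Oasl2, of the oligoadenylate synthetase family, stood at 7.27 ± 0.351 CPM in wild type and 2.34 ± 0.104 CPM in knockout (n = 3 each), a log2 fold change of -1.64 (SE 0.15). Usp18, which removes the ubiquitin-like protein ISG15, fell by 1.57 (SE 0.17). Psmb8, an immunoproteasome subunit gene, rose by 1.03 (SE 0.07), though it stood at -0.11 with total counts. The median was -0.80 and camera gave an adjusted p = 7.56e-06, and an adjusted p = 0.095 with an estimated correlation. With total counts the median was -1.93 and the list was again called lower.

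**Figure D2:**
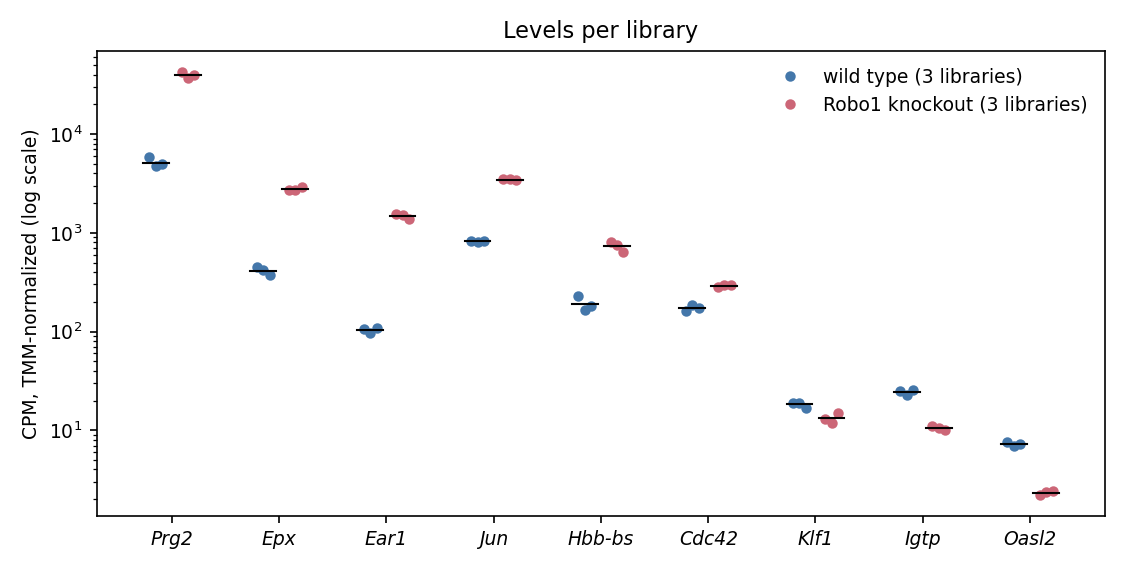
TMM-normalized CPM on a log axis for 9 genes in the 6 libraries, with black bars at the mean of each group of 3. Prg2, Epx, Ear1, Jun, Hbb-bs and Cdc42 were higher and Klf1, Igtp and Oasl2 lower in every knockout library; with total counts Cdc42 turns to lower (log2 -0.38).

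The study's title concerns self-renewal, and genes of stem cell identity gave 10 lower, 2 higher and 26 not passing of 38 (10 and 2 adjusted over the list alone). The transcription factor genes Hoxb4 (log2 -2.45, SE 0.55), Hlf (-0.83, SE 0.23) and Meis1 (-0.52, SE 0.15) were among those that fell. Ly6a, which encodes the stem cell antigen Sca-1, rose by 0.76 (SE 0.10), but was at -0.37, a call in the other direction, with total counts. The list itself was not called (median -0.28, camera adjusted p = 0.252). Of 20 genes of multipotent and lymphoid-primed progenitors 4 rose and 3 fell (4 and 3 adjusted over the list alone), with Plac8 at a log2 fold change of 2.11 (SE 0.07), and the list was not called (camera adjusted p = 0.798). Megakaryocyte and platelet genes gave 7 lower, 3 higher and 19 not passing of 29 (7 and 3 adjusted over the list alone; camera adjusted p = 0.166). The platelet glycoprotein genes Gp1bb (log2 -1.59, SE 0.32) and Gp5 (-1.68, SE 0.40) were among those that fell.

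The title also names erythropoiesis. Of 47 erythroid genes 8 rose, 4 fell and 35 did not pass (8 and 4 adjusted over the list alone), and the list was not called (camera adjusted p = 0.599). With total counts 4 members were called higher and 33 lower, at a median of -1.14. The globin gene Hbb-bs rose from 192 ± 34.0 to 736 ± 86.7 CPM (n = 3 each) and Hba-a1 from 781 ± 117 to 2450 ± 209 CPM, both also higher with total counts (log2 0.81 and 0.52). The globin gene copies can share reads. Klf1, an erythroid transcription factor, fell from 18.2 ± 1.20 to 13.2 ± 1.59 CPM (log2 -0.47, SE 0.11, edgeR adjusted p = 0.0123), and the blood group gene Rhd fell by 0.72 (SE 0.13). Gata1 stood at 22.2 ± 1.06 and 22.2 ± 4.26 CPM and did not pass. Of 35 genes of haem synthesis and iron handling 11 rose and 7 fell (11 and 10 adjusted over the list alone; camera adjusted p = 0.539), with the ferritin genes Ftl1 (log2 1.71, SE 0.06) and Fth1 (1.99, SE 0.09) higher and the iron-sulphur scaffold gene Iscu lower (-1.93, SE 0.18).

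Cdc42, a small GTPase named in the title (ENSMUSG00000006699, chromosome 4, 137319696 to 137357720), showed a direction that depended on the scaling. With TMM it rose from 174 ± 11.6 to 292 ± 7.19 CPM (n = 3 each), a log2 fold change of 0.75 (SE 0.07, edgeR adjusted p = 2.86e-05). With total counts its log2 fold change was -0.38, a call in the other direction. The deposited FPKM values were 105 ± 11.7 in wild type and 80.6 ± 2.83 in knockout (n = 3 each). The authors' deposited DESeq2 table gives Cdc42 a log2 fold change of 0.76 (SE 0.07, adjusted p = 1.79e-23) and classes it as stable, since that class takes in every log2 fold change within 1 of 0. Of 20 Slit-Robo genes 1 rose, the adaptor gene Nck2 (log2 2.44, SE 0.67), and 0 fell, while none passed adjusted over the list alone (camera adjusted p = 0.731). With total counts 0 of them were called higher and 16 lower, at a median of -1.24.

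Among 53 genes of adhesion, homing and the actin cytoskeleton 19 rose, 4 fell and 30 did not pass (21 and 5 adjusted over the list alone). Actb, cytoplasmic beta-actin, rose from 468 ± 57.4 to 6112 ± 797 CPM (n = 3 each), and Tmsb4x, which encodes an actin-binding thymosin, rose from 1180.0 ± 101 to 7976 ± 262 CPM. Cfl1, cofilin, rose by a log2 fold change of 1.96 (SE 0.05). These 3 genes were higher under both scalings, and Actb and Tmsb4x have pseudogenes that can share reads. The list was called at a median of 0.29 (camera adjusted p = 0.0023, and adjusted p = 0.273 with an estimated correlation), and with total counts, at a median of -0.84 with 8 members called higher and 39 lower, it was not.

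**Figure D3:**
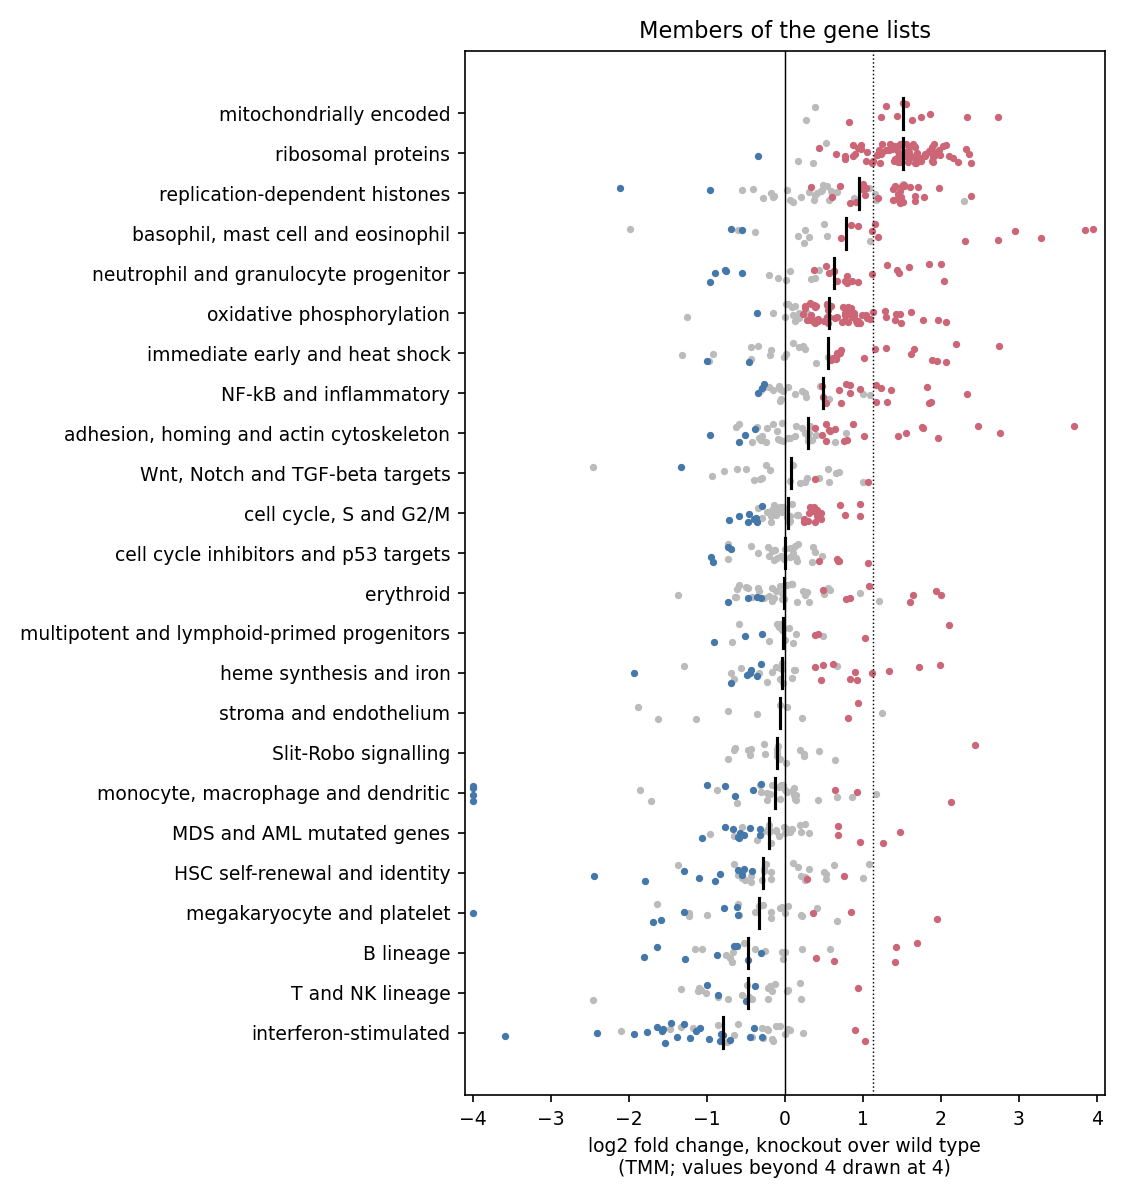
Log2 fold change of each member of 24 gene lists with TMM scaling (red, higher; blue, lower; grey, not passing), with the list median as a black bar. The dotted line at 1.13 marks the size of the median shift between TMM and total-count scaling; the ribosomal protein and mitochondrially encoded medians of 1.51 and 1.52 lie beyond it.

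Markers of other blood cells moved in part. Of 38 monocyte, macrophage and dendritic cell genes 3 rose and 9 fell (3 and 9 adjusted over the list alone; camera adjusted p = 0.303), with Ly6c2 higher (log2 2.12, SE 0.07) and Cd68 lower (-0.76, SE 0.08). Of 26 T and NK cell genes 1 rose and 4 fell (1 and 2 adjusted over the list alone), and the list was called lower (median -0.48, camera adjusted p = 0.0233, and adjusted p = 0.162 with an estimated correlation). With total counts its median was -1.61, with 0 members called higher and 21 lower, but camera did not call it relative to the other genes. The gene that rose, Nkg7 (log2 0.94, SE 0.05; -0.19 with total counts), is also on the neutrophil list, and Lck fell from 7.66 ± 0.855 to 3.83 ± 0.783 CPM. Stromal and endothelial genes gave 2 higher and 0 lower of 11 (2 and 0 adjusted over the list alone; camera adjusted p = 0.768). Of 27 B lineage genes 5 rose and 8 fell (5 and 8 adjusted over the list alone; camera adjusted p = 0.303). Igkc, the kappa light chain constant gene, rose from 10848 ± 454 to 35193 ± 875 CPM (n = 3 each), while the lambda constant gene Iglc1 fell from 341 ± 33.3 to 109 ± 11.3 CPM and Ebf1, a B cell transcription factor, fell by a log2 fold change of 1.80 (SE 0.51).

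Cell cycle genes gave 18 higher and 8 lower of 50 (19 and 10 adjusted over the list alone; camera adjusted p = 0.303), with Mcm6 at a log2 fold change of 0.77 (SE 0.06) and Mki67 at -0.37 (SE 0.07). All of the 18 that rose were below 0 with total counts, where 0 members were called higher and 48 lower. Of 35 cell cycle inhibitors and p53 targets 5 rose and 4 fell (5 and 4 adjusted over the list alone; camera adjusted p = 0.929), with Trp53 at 0.68 (SE 0.07; -0.45 with total counts). Of 37 genes mutated in myelodysplastic syndrome and acute myeloid leukaemia 5 rose and 10 fell (5 and 10 adjusted over the list alone; camera adjusted p = 0.574), with Npm1 at 1.26 (SE 0.06) and Dnmt3a at -0.52 (SE 0.10). Of 24 Wnt, Notch and TGF-beta targets 2 rose and 1 fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.831), the gene that fell being Tcf7l2 (log2 -1.33, SE 0.12). For 6 of the lists that were not called the median, the mean and the direction of the test differed in sign.

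Among called genes with a usual symbol, non-overlapping groups and a mean of at least 1 CPM, the largest rises belonged to immunoglobulin genes. Of the 10 largest, 9 were kappa V genes on chromosome 6 and 1 was Ear10. Igkv8-18 (70355852 to 70356445) had 0 counts in wild type and 2224 in knockout, at least 1694-fold higher with TMM scaling. With total counts that bound would be lower. Igkv8-34 stood at 0.125 ± 0.216 and 258 ± 4.47 CPM (n = 3 each). Among the 10 largest falls were 5 immunoglobulin V genes, led by Ighv9-1 on chromosome 12 at 47.4 ± 0.665 and 1.34 ± 0.262 CPM. Over all genes named as immunoglobulin V genes 125 rose and 19 fell with TMM scaling, and these counts were not made with total counts. Immunoglobulin genes together took 2.72 ± 0.0429% of all counts in wild type and 3.57 ± 0.0848% in knockout (n = 3 each). V genes are near-copies that can share reads, and their separate values are uncertain. Outside immunoglobulin genes, and within the same limits, the largest falls were Gemin4, a component of the SMN complex (5.54 ± 0.434 and 0.199 ± 0.137 CPM, log2 -4.85, SE 0.37), Atp23, Tbcc, Rbm42, Rtp4, Dnajb11, Atpaf1, Clptm1, P3h1 and Epdr1. The largest rises beside the Ear genes, Actb, Prg2 and Tmsb4x were Lars2, Pde2a and H2-Q4. Lars2 differed within wild type, at 0.0732% of counts in replicate 1 and 0.0214% to 0.0234% in the others. Replicate 1 also held 0.345% of counts on ribosomal RNA genes against 0.0781% in wild type replicate 2. Between groups the 2 shares did not go together. The knockout libraries held 0.177% to 0.236% on Lars2, but only 0.0518% to 0.106% on ribosomal RNA genes.

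**Figure D4:**
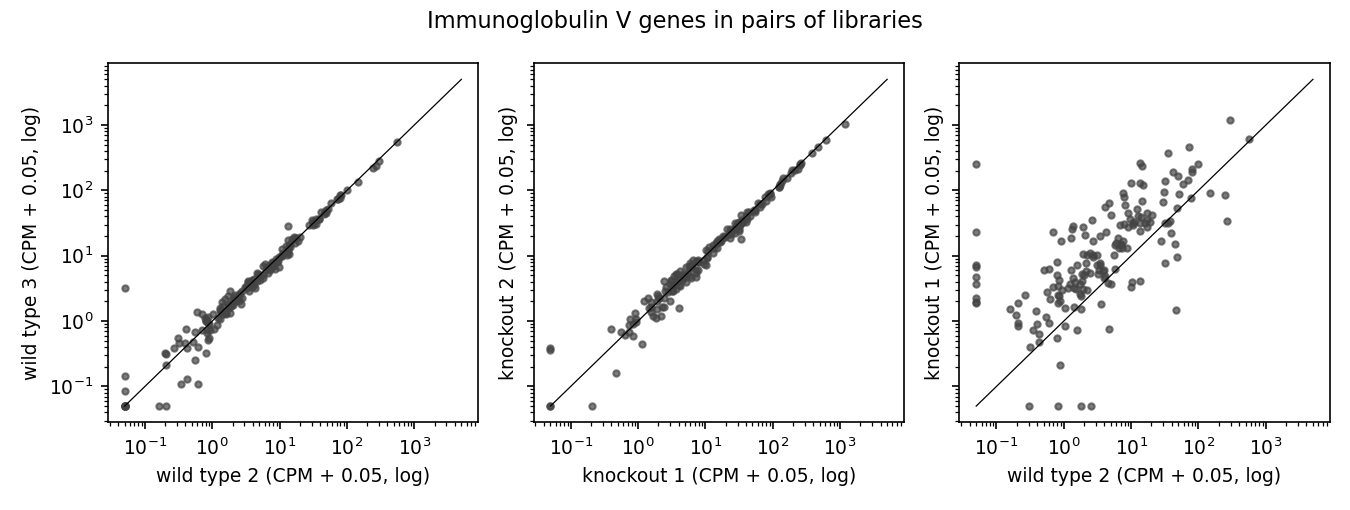
Immunoglobulin V genes in CPM + 0.05 on log axes, each point 1 of 171 genes, in wild type replicates 2 and 3, knockout replicates 1 and 2, and wild type replicate 2 against knockout replicate 1. Points follow the line of equality within a group and scatter between groups.

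The authors' deposited comparison classes 1519 genes as higher, 889 as lower and 16083 as stable. These classes match an unadjusted p under 0.05 with a log2 fold change beyond 1 in either direction for every row. With the table's own adjusted p under 0.05 in place of the unadjusted one, 1318 of the higher and 564 of the lower genes remain.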

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

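The scaling by total counts, the removal of immunoglobulin genes and the length and GC correction were chosen after seeing the data. Against 4898 changed genes, 2669 higher and 2229 lower, the other planned scalings, filters, dispersions and test programs gave 4762 to 4994 changed genes, and DESeq2 shared 4717 of its 4994 calls. An adjusted p under 0.1 gave 5951 changed genes. Leaving out each library in turn gave 3582 to 4656 changed genes, 2226 to 2542 higher and 1356 to 2142 lower. Each time 11 lists were called. The lowest counts came without wild type replicate 2, while 4315 genes changed without wild type replicate 1. All of these fits tested equally many libraries. Wild type replicate 1 differed from replicates 2 and 3 by a chi-square per gene of 39.4 and 38, against 13.8 between replicates 2 and 3. Asking for a 2-fold change left 1812 genes, 1278 higher and 534 lower. With the replicate number as a block 4373 genes changed and 11 lists were called, but the numbers did not pair the libraries, since the deviations of same-numbered libraries correlated at 0.05, -0.04 and 0.00 (over 7898 genes, which are not independent replicates) and not every library correlated best with its own number. With an estimated correlation camera called 0 of 25 lists (7 at an unadjusted p under 0.05), against 11 with the preset value and 19 with fry, which does not compare a list with other genes.

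Total counts alone gave 11592 changed genes, 655 higher and 10937 lower, with the median log2 fold change moved by -1.13. Among the 127 genes named by the rule, those called under either scaling that turned from above to below 0 were Cdc42 -0.38, Trp53 -0.45, Btg2 -0.46, Mcm6 -0.36, Ccna2 -0.17, Ube2c -0.17, Rrm2 -0.42, Car1 -0.0583, Hp -0.0168, Ly6a -0.37, Psmb8 -0.11, Sf3b1 -0.18, U2af1 -0.45, Pf4 -0.77, Cst3 -0.21, Vcam1 -0.50, Emb -0.11, H2bc4 -0.22, Xist -0.92, Igfbp4 -0.19, Vim -0.32, Spp1 -0.91, Nkg7 -0.19, Myc -0.0638 and Id2 -0.75. The cell cycle list, not called before, was called lower at an adjusted p = 0.00115 (0.000263 to 0.655 over its 17 alternatives, the lowest being a call as higher with the length and GC correction). With the length and GC correction 4789 genes changed, 3824 of them shared, Pf4 turned to -0.49, and camera, which compares a list with the other genes, called the MDS and AML list higher at an adjusted p = 0.0485 and a median of -0.07 (0.0485 to 0.795 over 17 alternatives) and the histone list lower at an adjusted p = 0.0108 and a median of 0.11 (1.48e-09 to 0.493). Apart from the shift, the cause was not tested. Of the 127 named genes, Nck2, Ccl5 and Ms4a4b lost their calls without 1 or more of the single libraries, and calls were also lost for Hoxb4 with limma-voom, Ccl5 with RLE scaling, Nck2 with the replicate block and total counts, Ccl3 with total counts and Ly6a with the length and GC correction.

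The other settings for the Robo1 level were not run because the gene was not analysed here, and the change of pseudocount was not run because counts were tested. In the simulation, where 200 of 14643 genes changed, 26.9% of 1.5-fold changes were called. A far larger share of genes was called in the real comparison, so this percentage does not carry over to it, though small changes can be missed.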

Other observations

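The tests of immunoglobulin usage, of the most abundant genes and of the Robo1 neighbourhood were chosen after the results were seen. The predictions of the length and GC, matched-list and regrouping tests were set before the results of those tests were seen. The length and GC correction itself was added after the data were seen, and the matched lists address a trend already seen in them.

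Immunoglobulin constant genes moved apart from one another. Ighg3 rose from 2.37 ± 0.717 to 47.0 ± 2.48 CPM (n = 3 each) and Ighg1 fell from 22.3 ± 1.55 to 7.53 ± 0.619 CPM, while Ighg2c stood at 35.6 ± 3.84 and 36.3 ± 1.08 CPM and did not pass. Ighm, the IgM heavy chain gene, rose by a log2 fold change of 1.42 (SE 0.05) and Igha, that of IgA, by 1.40 (SE 0.06), both also higher with total counts (0.29 and 0.26). Xbp1, a transcription factor of plasma cells, fell by 1.29 (SE 0.20).

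Several genes of macrophages and dendritic cells were low in wild type and had 0 counts in the knockout libraries. Itgax, which encodes CD11c, had 116 counts in wild type and was at least 16.9-fold lower in knockout, Spic with 68 counts at least 9.92-fold lower, Fcgr1 with 66 counts at least 9.63-fold lower, and Ms4a7 with 83 counts at least 12.1-fold lower. With these genes at their bounds the median of the monocyte, macrophage and dendritic list stayed at -0.13. Xist, on the X chromosome, stood at 70.4 ± 9.32 CPM in wild type and 81.7 ± 4.42 CPM in knockout (n = 3 each) and did not pass with TMM.

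Across 171 immunoglobulin V genes the correlation of log2 CPM was 0.969 to 0.987 between libraries of a group and 0.675 to 0.700 between groups, whereas other genes of the same level gave 0.937 to 0.947 between groups (genes are not independent replicates). V genes missing from the germline or the reads of one group are not the whole of it, because over V genes with at least 100 counts in every library the mean correlation between groups was still 0.721, against a lowest value of 0.987 within groups. The median coefficient of variation of V genes between libraries was 10.5% in wild type and 7.02% in knockout, at most 1.39 times that of other genes of the same count level, which restates the likeness within groups and does not test its cause. Whether the libraries of a group share one source of RNA, such as one animal or one pool, stays open, as does an untested effect of genotype on the antibody repertoire.

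Abundant transcripts were higher and the median transcript lower as a share of counts in knockout. The most abundant genes carry part of it: the median log2 difference was -1.15 with all genes in the totals, -0.69 with the 100 most abundant left out and -0.36 with 500 left out, so a few dominant genes are not the whole of it. Nor does transcript length and GC content account for all of it: the gap between the most abundant eighth of genes and the others was 0.62 on the log2 scale before the correction and 0.496 after it (95% bootstrap interval over genes 0.453 to 0.533). That interval resampled genes, which are not independent replicates, with the libraries and the correction held fixed. It does not measure the spread between libraries. Genotype, cell mixture and library preparation remain open, and the labels name no batch that would separate them.

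Because fold changes rose with abundance, the lists were set against 10000 random lists matched on abundance and exon length. The ribosomal protein median of 1.51 lay at percentile 100 of the matched lists (median 0.82), and that of basophil, mast cell and eosinophil genes at percentile 99.06. Members of the random lists were drawn independently, so the matched lists leave out correlation between genes, estimated at 0.58 for ribosomal protein genes and -0.033 for the basophil list. The percentiles can overstate how far a list of correlated genes stands out. They do not by themselves exclude the abundance and length trend. The oxidative phosphorylation median lay at percentile 4.26, below the matched median of 0.79, that of neutrophil genes at percentile 79.3 and that of mitochondrially encoded genes at percentile 90.35, so for these lists the trend may account for the rise. Of the other called lists, interferon-stimulated genes lay at percentile 0, T and NK cell genes at 1.43, histones at 99.81, immediate early and adhesion genes at 99.99 each, and NF-kB genes at 100. Among lists that were not called, B lineage genes lay at percentile 0.04 and Wnt, Notch and TGF-beta targets at 98.84. A biological change in eosinophil progenitors remains a hypothesis, since differences in the sorted cell mixture were not separated from genotype.

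The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 4898 changed genes and the highest other split 1; for gene lists the real split gave 11 calls and the highest other split 8. In each case 1 of the 10 splits, the real one, gave a result as large. Every other split mixes wild type and knockout libraries, so the difference between groups adds to the spread within its sides and lowers its calls. The contrast with those splits therefore does not measure support for an effect of genotype.

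A further hypothesis was that DNA flanking the modified Robo1 allele might carry expression differences. Of 99 tested genes within 20 Mb of Robo1, 38 were called (38.4%, against 31.6% elsewhere, two-sided Fisher's exact p = 0.159), which leaves it open.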
